A study of Mus musculus with 2 samples.

How the data were processed

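The 2 libraries used were H3K36me3 chromatin immunoprecipitation from pooled embryonic day 14.5 mouse intestine, biological replicates 1 and 2, each with 1 technical replicate. Per the labels, the pools held 24 and 34 embryos of mixed sex. The labels name an experiment that could serve as control; its data were not analysed here.

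For each replicate the authors deposited a peak list in narrowPeak format. They also deposited a list made from the alignments of both replicates together and a list of replicated peaks derived from the other 3. Per the notes deposited with the samples, all lists are on build mm10. The list of replicate 1 came from its alignments and 2 further files whose role is not stated, and that of replicate 2 from its alignments and 1 further file. The aligner, the peak caller, their versions and the rule for a replicated peak are not given in the sources used here. In the lists, all 114793 replicated peaks were identical to a peak of the list from both replicates together, and 75.4% of them overlapped the lists of both single replicates. Each deposited line gives a score, which was not used. The deposited fold enrichment is a ratio of the peak's signal to its background as the authors computed it. The deposited significance is given as −log10 of a p-value and −log10 of a q-value. The lowest −log10 p, rounded, was 2.01 and the lowest −log10 q 0.599, both in replicate 2. The lists hold no read counts, so depth per library is unknown and no interval from counting error can be given. Fold enrichment was used to rank and describe peaks, as a mean of both replicates for genes, and to match peaks of similar height between the replicates' lists. Its scale is assumed to be the same in both. A peak list shows where signal passed a threshold that depends on depth, so a difference in covered length between replicates is not a difference in the amount of the mark. A gene with no peak lacks detected signal at the authors' threshold.

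Peak positions were intersected with the GENCODE M21 annotation of GRCm38, the assembly also named mm10, on 19 autosomes, X and Y. Chromosome lengths came from the RefSeq annotation of the same assembly, and no peak ended beyond its chromosome. Coordinates are given from 1. Peaks on scaffolds without a position in a chromosome were left out of all comparisons. Overlapping peaks of a list were merged before counting base pairs. Features were assigned in the order coding sequence, 3' UTR, 5' UTR, other exon, intron of a protein-coding gene, intron of another gene, 1 kb upstream of a protein-coding gene, and intergenic. Gene body coverage is the percent of the span from annotated start to end that lies in peaks. It was measured in 21911 protein-coding genes, the longest being kept where a symbol was given to more than 1 gene. Peaks carry no strand, so overlapping genes share covered sequence, and this is stated for the named genes with at least 5% of their covered sequence in another protein-coding gene. Values are means of the 2 replicates with their SD.

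The expected overlap of lists came from 100 random circular shifts of each chromosome's peaks. A gene was called marked at 25% coverage in each replicate, and intergenic windows of gene length gave the background. Gene profiles used 10 bins in genes of at least 5 kb. Each of 24 gene lists and 5 gene families was compared, by the median of its members' mean coverage, with 10000 random lists of equal size drawn from 20 classes of gene length. It was called higher at percentile 97.5 or above and lower at 2.5 or below. These percentiles describe these libraries and are not p-values, because genes are not replicates. With 1 group there was no test between groups. Of the fixed symbols, 8 were non-coding genes and were not part of the lists measured, 1 (Mrg15) was not found, and 4 were matched through older names. There were 9 symbols in more than 1 list. The list of X-linked and Y-linked genes kept for lookup had 13 measured members with a median of 0.226%, at percentile 22.9.

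The genes named were set by a rule fixed before the data were examined: from each list the 2 members with the highest and the 1 with the lowest mean coverage, 15 genes of at least 5 kb with the highest coverage share times mean fold enrichment, the 10 replicated peaks of largest fold enrichment, and the 5 genes furthest apart between replicates in each direction, with ties broken by symbol. Any marked member of a list of unsampled tissues was also to be named, and there was none. The alternatives fixed at the same time were a q-value of 0.01, lists of equal length, other overlap rules, joining peaks within 1 kb, the authors' other lists, each replicate left out, other coverage thresholds, other gene sets and other random lists.

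The measurements other than the list test were tested on simulated peaks over the same 21911 genes. Covered base pairs matched a base-by-base count in all 718 genes of chromosome 19. All 200 genes given peaks were called marked, and 0.594% of the other 21711 were called with shifted peaks. The peaks were set by the simulation, so the result for the 200 genes checks the calculation and not the sensitivity to weaker signal. These values describe simulated peaks and are not error rates of the calls in these libraries. The list test was tried on random lists with the real coverage of these libraries. Of 100 lists with no effect, 5% were called by the median, and of 100 lists with 15 of 30 genes from the 10% most covered, 100%. Those 15 genes were picked by the same coverage that was tested. The 100% therefore checks the calculation and does not measure the power of the list test. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.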

Results

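Chromatin immunoprecipitation followed by sequencing measured H3K36me3, a histone H3 methylation mark placed behind elongating RNA polymerase II, in the intestine of mouse embryos at embryonic day 14.5. There was 1 group with 2 biological replicates, made from pooled tissue of 24 and 34 embryos of mixed sex. No second tissue, stage or genotype was part of the series, so the comparisons are between replicates, between parts of the genome, and between groups of genes fixed before the data were examined. The deposited data were peak lists on mouse build mm10. Replicate 1 held 162148 peaks covering 112 Mb (4.12% of the chromosomes) and replicate 2 held 163812 peaks covering 90.5 Mb (3.32%). The authors' list from both replicates together held 170884 peaks, and their list of replicated peaks 114793. Read numbers were not given in these lists, so the sequencing depth behind each value is unknown.

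The mark lay over genes. Of the peak base pairs, 96.3% ± 0.0505 (SD, n = 2) fell within annotated genes, which make up 44.8% of the chromosomes. This was a 2.15-fold enrichment (SD 0.00113, n = 2), against 1.01-fold to 1.13-fold in 100 random circular shifts of the peaks along their chromosomes. Coding sequence was enriched 8.20-fold ± 0.477 (SD, n = 2) over its share of the chromosomes and 3' UTRs 6.24-fold ± 0.0155. Introns of protein-coding genes were enriched 2.05-fold ± 0.0201 and held most of the covered sequence, 70.3% ± 0.688 of peak base pairs. Depleted were 5' UTRs at 0.617-fold ± 0.00583, the 1 kb upstream of protein-coding genes at 0.0849-fold ± 0.00251 and intergenic sequence at 0.0668-fold ± 0.000951. Each of these departures from 1 exceeded the difference between replicates.

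**Figure D1:**
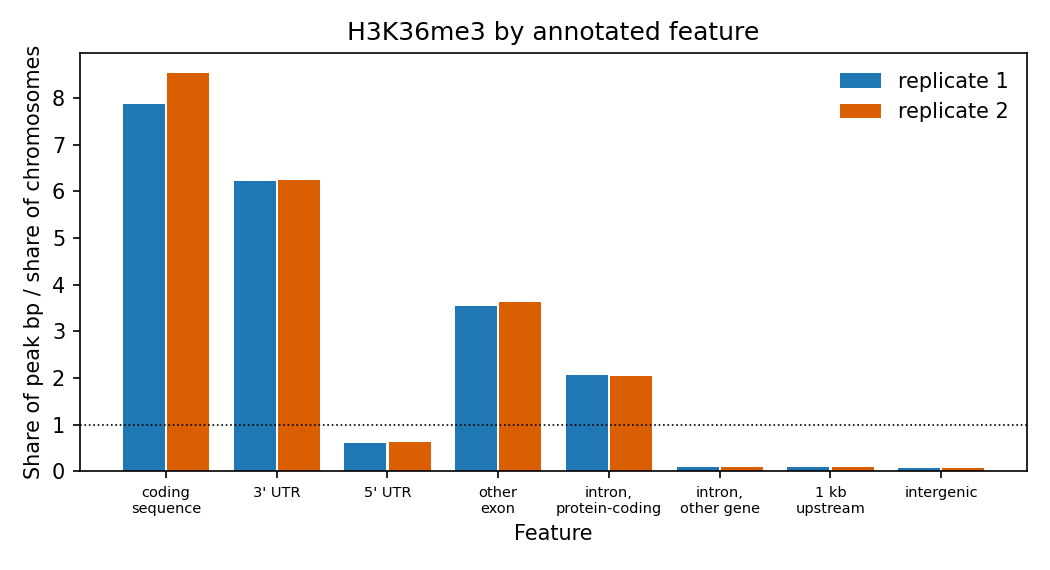
Enrichment of peak base pairs by annotated feature (x axis), as the share of peak base pairs divided by the feature's share of the chromosomes (y axis, no unit), with 1 bar per replicate and a dotted line at 1. Coding sequence and 3' UTRs stand at 8.20-fold and 6.24-fold on average, and intergenic sequence at 0.0668-fold.

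Within genes the covered share grew from the transcription start toward the end. In the 17779 protein-coding genes of at least 5 kb, gene bodies were divided into 10 bins. Bin 1 was covered to 2.37% ± 0.425 (SD, n = 2) and bin 9 to 24.0% ± 2.66. Coverage of bins 6 to 10 was 2.01 times that of bins 1 to 5 (SD 0.0420, n = 2). In the 4577 marked genes of at least 5 kb, coverage went from 6.10% ± 1.07 in bin 1 to 69.9% ± 5.98 in bin 9, then 64.2% ± 6.55 in bin 10. Exons of marked genes were covered to 62.5% ± 5.79 and their introns to 45.7% ± 5.82. The exon share was above the intron share in each replicate (66.6% against 49.8% in replicate 1, 58.4% against 41.6% in replicate 2). Exons and introns were not matched on position along the gene, so this difference was not separated from the rise toward the end.

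**Figure D2:**
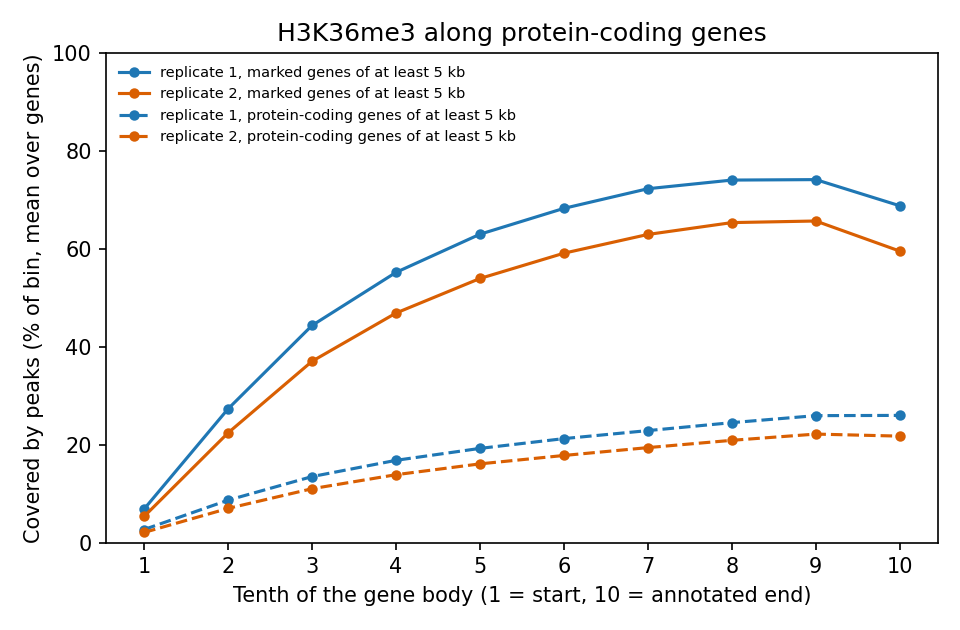
Mean share of each of 10 bins of the gene body covered by peaks (y axis, percent), from the annotated start (bin 1) to the annotated end (bin 10), with 1 line per replicate. Solid lines are the 4577 marked genes of at least 5 kb and dashed lines all 17779 protein-coding genes of that length; coverage is lowest in bin 1 in both sets.

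A gene was called marked when at least 25% of its body was covered in each replicate. Of 21911 protein-coding genes, 5011 (22.9%) were marked, and 10543 had no peak base pair in either replicate. The median coverage of the marked genes was 54.2% in replicate 1 and 46.0% in replicate 2. Among 21301 intergenic windows of the same lengths, 8 (0.0376%) passed the same rule. Gene length mattered: 34.5% of genes between 17.4 and 25.2 kb were marked, against 4.88% of genes up to 2.75 kb and 3.88% of genes of 110 kb or more. For this reason gene groups were compared with random lists of matched length. Other gene types carried the mark mostly where they overlap a protein-coding gene: 327 of 2959 antisense genes were marked, but 1 of the 209 that overlap none. Of 5358 long intergenic RNA genes free of such an overlap, 30 were marked. The number of marked genes depended on the rule, with 2001 genes at 50% of the body.

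Among the fixed lists, those taken as ubiquitous (spliceosome, cell cycle, ribosomal proteins and oxidative phosphorylation) had the highest coverage. All 40 measured spliceosome and RNA processing genes were marked, against an average of 12.1 in length-matched random lists. Their median coverage was 70.7%, above all 10000 random lists. Prpf8, a core component of the spliceosome, was covered to 90.6% ± 2.75 (SD, n = 2) and Sf3b3 to 90.0% ± 3.70, while Prpf40a had the lowest value at 42.2% ± 8.83. Of 35 cell cycle and DNA replication genes, 32 were marked against 9.69 on average at random, with a median of 61.5%, also above every random list. Top2a, the DNA topoisomerase of dividing cells, reached 86.1% ± 4.42 and Rrm1, a subunit of ribonucleotide reductase, 84.7% ± 4.89. The 3 members not marked were E2f1 at 26.3% ± 14.9, Rb1 at 2.11% ± 0.623 (75.2% of it within Rcbtb2 or Lpar6) and the X-linked Pola1 at 1.23% ± 0.282; E2f1 and Rb1 fall outside the naming rule and were chosen after their values were seen.

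Cytosolic ribosomal protein genes and oxidative phosphorylation genes were also covered above all 10000 random lists. Of 54 ribosomal protein genes 46 were marked (8.67 on average at random), with a median of 55.9%. Rps5 reached 79.5% ± 0.708 (SD, n = 2) and Rps3 79.3% ± 4.02, and the X-linked Rpl10 was lowest at 0.710% ± 1.00. Of 30 oxidative phosphorylation genes 24 were marked (7.55 at random), with a median of 54.2%. Uqcrc2, of respiratory complex III, reached 80.4% ± 7.14 and Atp5b, of ATP synthase, 80.1% ± 2.36. The X-linked Ndufa1 had no peak in either replicate. The 28 replication-dependent histone genes were not called higher or lower by their median, at percentile 50. None was marked (1.56 on average at random), 27 had no peak, and Hist1h2bc had 1.15% ± 1.62. The marked count lay at percentile 8.99, within the range of 0 to 4 of length-matched random lists. Only the list mean, at percentile 1.65, was low for genes of this length.

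Among cell types of the gut wall, the mesenchymal list was called higher than random lists. Of 35 gut mesenchyme genes 15 were marked against 6.89 on average at random, and the list median of 17.3% lay at percentile 99.9 of random lists. Among genes with at least 1 peak the mesenchymal list lay at percentile 97.56, just above the threshold for a call of higher. Fn1, which encodes the matrix protein fibronectin, was covered to 78.4% ± 11.2 (SD, n = 2) and Col6a1, a collagen VI chain, to 77.3% ± 3.43, while Barx1 had no peak. Visceral smooth muscle genes had a median of 15.6%, at percentile 93.5, which did not reach the threshold for a call of higher, and 5 of 16 were marked against 3.82 at random. Against random genes with at least 1 peak the list lay at percentile 20.7. Tpm1, a tropomyosin, stood at 63.4% ± 6.60 and the X-linked Flna, an actin crosslinker, at 60.6% ± 5.81. Lmod1 was lowest at 1.11% ± 0.0327.

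Epithelial genes carried little of the mark over their bodies. Of 40 gut epithelium genes, 1 was marked, against an average of 9.24 in random lists. It was Esrp2, an epithelial splicing regulator, at 39.0% ± 2.66 (SD, n = 2), and 8.43% of its covered sequence also lay in Nfatc3. The endoderm transcription factor Gata6 followed at 19.8% ± 0.878. Cdx1, an intestinal transcription factor, had no peak. Peaks were nevertheless frequent, since 9 of the 40 genes had none. The list median of 1.68% lay at percentile 64.0 of random lists and was not called. The list mean of 4.80% and the marked count both lay at percentile 0.02, the latter a measure added after seeing the data. Of 29 genes of differentiated enterocytes, goblet, Paneth or endocrine cells none was marked (6.04 at random) and 26 had no peak. The median of that list was 0, at percentile 39.9, and was not called. Lct, which encodes lactase, had 4.37% ± 0.891, Apob 2.36% ± 1.7 and Agr2 no peak.

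Lists of further cell types of the gut had no marked member. This held for 25 genes of the enteric nervous system (5.73 on average at random), 20 of endothelium (4.37), 24 of blood and macrophages (4.02) and 9 of mesothelium and interstitial cells of Cajal (2.16). Within them the highest coverage was that of Ednrb at 7.81% ± 4.34 (SD, n = 2) and Erbb3 at 6.54% ± 0.336 in the neural list. Eng, an endothelial co-receptor, had 9.63% ± 0.312 and Egfl7 7.76% ± 0.949, but all of the sequence covered in Egfl7 also lay in Agpat2 or another overlapping gene. Cx3cr1 had 16.1% ± 0.787, with all of it inside 5 overlapping protein-coding genes such as Wdr48, and Fcer1g 14.1% ± 3.17. Kit, the receptor of interstitial cells of Cajal, had 12.6% ± 4.18 and Ano1 5.75% ± 2.12. Ascl1, Cdh5, Adgre1 and Lrrn4 had no peak. The medians of these 4 lists were 0 and were not called lower, because a median cannot fall below the 0 that many random lists also had. Their list means lay between percentiles 0 and 1.83.

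Genes of organs next to the gut and of tissues that were not sampled gave the background of the same measurement. None of 25 genes of stomach, pancreas, liver or lung was marked (5.59 on average at random), and the highest were Sftpb at 4.42% ± 1.42 (SD, n = 2) and Ttr at 3.48% ± 0.375. Afp had no peak. The 25 central nervous system genes reached 5.05% ± 0.318 at most, in Mog, followed by Mbp at 0.793% ± 0.152, with no peak in Aqp4. Of the 25 genes of striated and heart muscle, Ryr1 alone had a peak, at 0.189% ± 0.268, and Acta1 had none. The same was true of Dmc1 among 25 germ cell genes, at 0.468% ± 0.661, with none in Acrv1. In the epidermis and photoreceptor list Opn1sw had 14.5% ± 1.36, with 25.6% of its covered sequence also in Calu, and Pde6b 3.90% ± 0.569, and Crx had no peak. None of these 5 lists held a marked gene, and none was called by its median, which was 0 in each. Olfactory receptors (1134 genes, Olfr1 and Olfr10 among them), vomeronasal receptors (328, with Vmn1r1 and Vmn1r10), keratin-associated proteins (57, with Krtap1-3 and Krtap1-4) and defensins (64, with Defa17 and Defa2) had no peak base pair in either replicate.

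Developmental regulators were divided. None of 39 Hox genes was marked, against 7.31 on average at random, and 30 had no peak, Hoxa1 among them. By the planned measure, the Hox list median was 0, at percentile 47.8, and was not called. Hoxb4 was highest at 24.4% ± 1.03 (SD, n = 2) and Hoxa5 had 11.4% ± 3.72, all of it within overlapping genes that include Hoxa3. Of 41 genes of the Hedgehog, Wnt, BMP, Notch and FGF pathways, 14 were marked against 7.55 at random, and the median of 19.2% lay at percentile 99.98. Among pathway genes with at least 1 peak the list lay at percentile 86.6 and the call was lost. Ptch1, the Hedgehog receptor, had 61.1% ± 4.57 and Smad5, a BMP signal transducer, 48.7% ± 7.56. Id1 had no peak. Of 31 protein-coding imprinted genes 6 were marked, against 5.87 at random, with a median of 8.03% at percentile 95.9. Among genes with at least 1 peak the imprinted list lay at percentile 1.39, so the direction turned. Igf2r had 54.7% ± 5.90 and Magel2 none. Mcts2 had 62.6% ± 16.9, all of which lay within H13, the gene that contains it.

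Genes that write, read or erase H3K36 methylation, and those of DNA methylation and Polycomb, were marked more often than random lists. Of 30 measured H3K36 genes 21 were marked (7.24 on average at random), with a median of 48.9%, above every random list. The demethylase gene Kdm4a had 84.6% ± 0.714 (SD, n = 2), Glyr1 84.0% ± 5.33 and Phf19 4.09% ± 2.63. Setd2, which encodes the enzyme that places this mark, had 55.3% ± 7.11 and was chosen after its values were seen. Of 26 DNA methylation and Polycomb genes 17 were marked (6.72 at random), with a median of 39.9% at percentile 99.99. Rbbp4, a histone chaperone, had 75.1% ± 8.71, with 5.74% of its covered sequence also in Sync, and Uhrf1, the partner of the maintenance DNA methyltransferase, 69.3% ± 6.44. Cbx7 had 0.440% ± 0.0447. Zinc finger genes named Zfp formed the largest group above random: 158 of 394 were marked against 115, with a median of 20.2%, above all random lists. Zfp869 had 89.2% ± 6.58, and Zfp606 84.0% ± 6.49, while Zfp114 was among 73 with no peak. Among genes with at least 1 peak the Zfp list lay at percentile 8.50, so the direction turned, and it was not called.

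**Figure D3:**
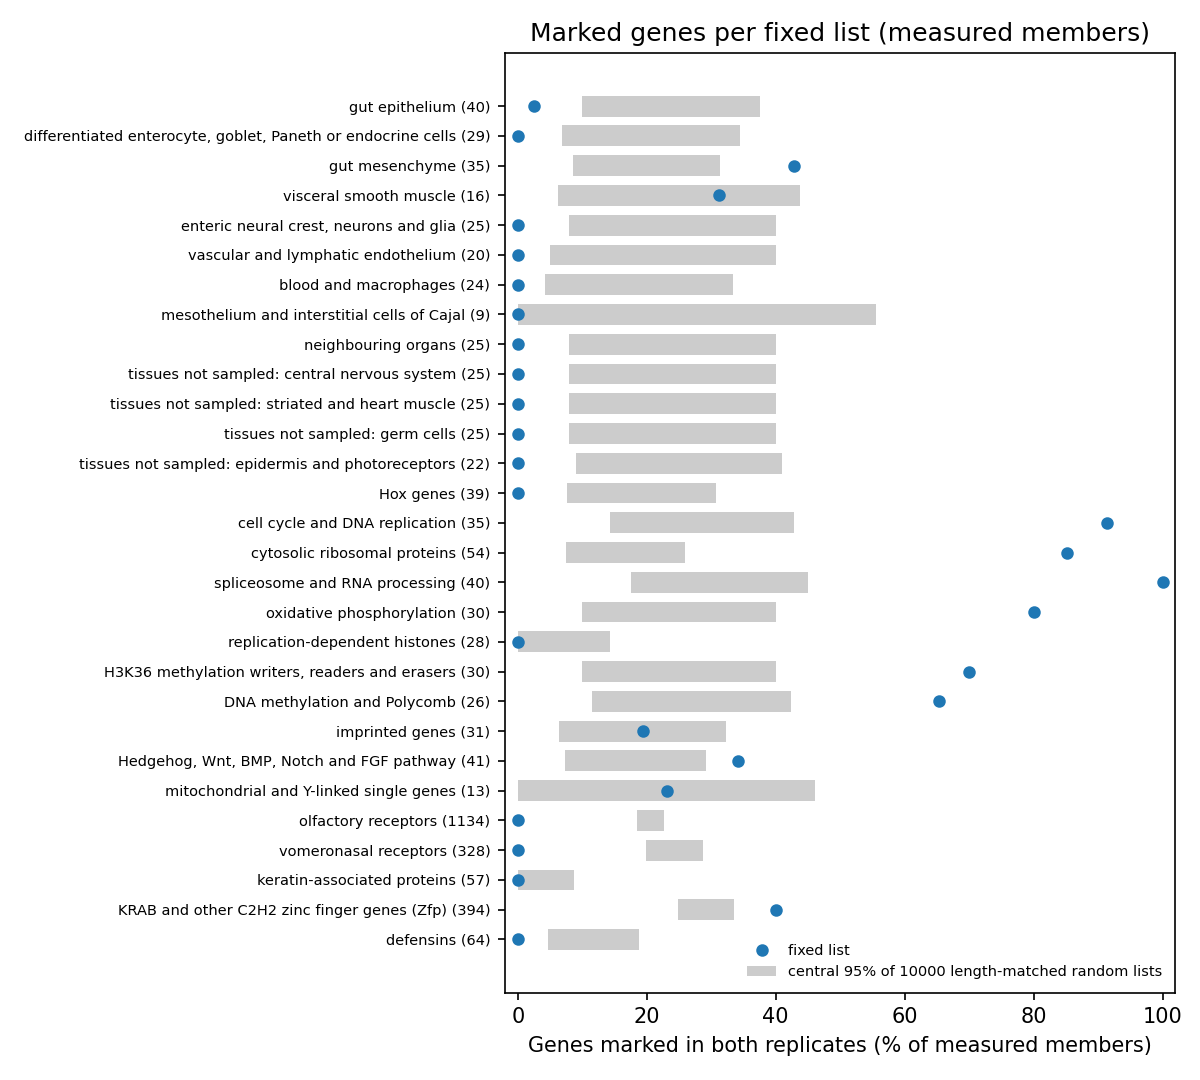
Share of measured members marked in both replicates (x axis, percent) for each fixed list or family (y axis, number of measured members in parentheses). Dots are the lists and grey bars the central 95% of 10000 length-matched random lists; spliceosome genes stand at 100%, and gut epithelium genes, with 1 of 40 marked, lie below their bar.

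Ranked by coverage share times the mean of the authors' fold enrichment for the peaks in the gene, the first 15 genes ran from Hnrnpab (6.58) to Prpf8 (5.72). Hnrnpab, an RNA-binding protein gene at chromosome 11, 51600100 to 51606847, was covered to 77.4% ± 3.89 (SD, n = 2) with a mean fold enrichment of 8.52 ± 0.609, and 84.1% of its covered sequence also lay in the overlapping gene Phykpl. Second was Zfp606 (chromosome 7, 12478293 to 12496235) with a fold enrichment of 7.77 ± 1.71, and the third was the ribosomal scaffold gene Rack1 (chromosome 11, 48800332 to 48806434) with 7.99 ± 2.25. The others were Calr, Rbm5, Zfp68, Cdc25a, Rabggtb, Ddb1, Bap1, Prmt5, Ccnl2, Kmt2b and Eif4g2, with coverage between 73.8% in Calr and 88.5% in Ddb1.

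Individual peaks were tallest in zinc finger genes. The replicated peak with the largest fold enrichment given by the authors, 14.1, lay at chromosome 5, 138454317 to 138459449, with its summit in a coding exon of Zfp157. The next was a peak of 12.8 at chromosome 10, 79064103 to 79068832, with its summit in a coding exon of 2610008E11Rik. Further summits lay in an intron of Zfp68 (12.3; chromosome 5, 138610336 to 138612302), an intron of Zfp606 (12.03; chromosome 7, 12483415 to 12494438) and a coding exon of Zfp27 (11.9; chromosome 7, 29891908 to 29896952). Srrm2, which encodes a splicing factor, held a peak of 11.6 at chromosome 17, 23806778 to 23824359, with its summit in a coding exon. Zfp260 followed with its summit in a 5' UTR (11.6; chromosome 7, 30103581 to 30108165), and Gtf3c1, of RNA polymerase III transcription, in a coding exon (11.6; chromosome 7, 125691884 to 125704451). Hnrnph1 (chromosome 11, 50381992 to 50384022) and Zfp37 (chromosome 4, 62191062 to 62194873) each held a peak of 11.4 over a coding exon. Of these 10 peaks, 6 lay in genes named Zfp.

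The sex chromosomes differed from the autosomes. Peaks covered 4.08% ± 0.618 (SD, n = 2) of the autosomes, 0.631% ± 0.140 of the X chromosome and 0.00683% ± 0.000829 of the Y chromosome. On the X chromosome 36 of 948 protein-coding genes (3.8%) were marked. Across the 19 autosomes the marked share ran from 18.6% on chromosome 14 to 29.4% on chromosome 8. None of the 183 Y-linked genes was marked. Among X and Y genes fixed for lookup, Kdm5c had 58.4% ± 9.20 and Ddx3x 55.9% ± 6.75, and Eif2s3y, the Y-linked partner of Eif2s3x, had no peak. Xist, the non-coding RNA of X inactivation, was covered to 3.99% ± 1.93, all of it also within the annotated gene Gm26992. Mixed sex of the pools means that these values average male and female cells.

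**Figure D4:**
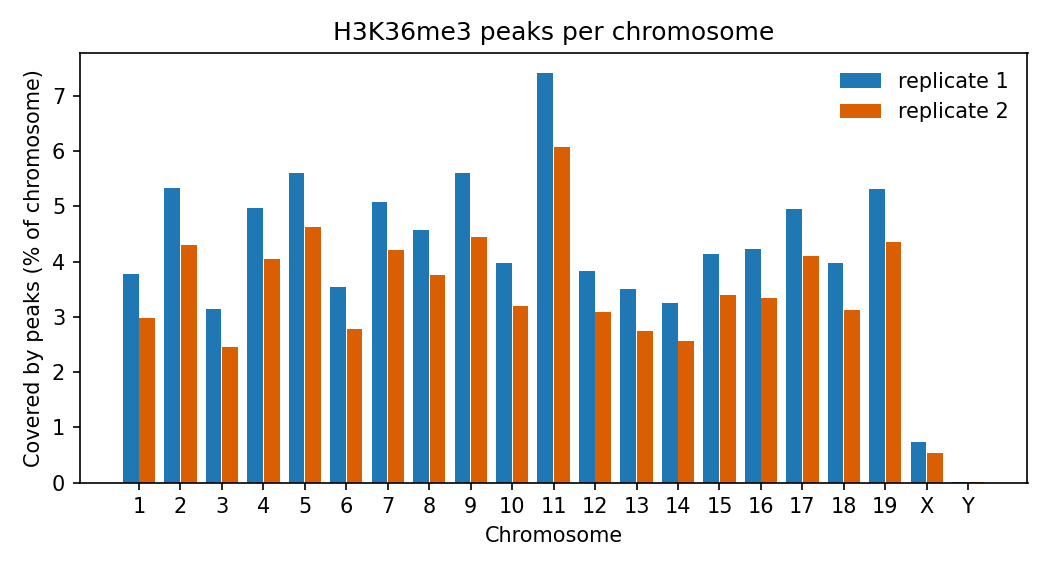
Share of each chromosome covered by peaks (y axis, percent) for chromosomes 1 to 19, X and Y (x axis), with 1 bar per replicate. The X chromosome stands at 0.729% in replicate 1 and 0.532% in replicate 2, below each autosome, and the Y chromosome near 0.

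The replicates shared most of their marked sequence. Of replicate 1 peaks, 67.6% overlapped a replicate 2 peak by at least 1 bp, and 80.4% of replicate 2 peaks overlapped replicate 1. Random circular shifts gave at most 7.85% and 8.63%. The replicates had 69.8 Mb in common, 52.5% of the sequence covered in either (at most 2.83% in shifts). When each of the overlapping peaks had to cover 50% of the other, the shares were 32.3% and 32%. Peaks that did not overlap were narrower and lower: in replicate 1 their median width was 285 bp, against 566 bp for overlapping peaks, and their median fold enrichment 3.25 against 4.09. Gene body coverage correlated between replicates with a Spearman's rho of 0.967 across 21911 protein-coding genes, which are not independent replicates.

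Single genes could still differ between replicates, and the larger differences favoured replicate 1. The gene with the widest gap was Aste1, covered to 48.9% in replicate 1 and 11.8% in replicate 2, with 60.1% of its covered sequence also in Nek11 or Atp2c1. It was followed by Med7 (63.6% and 27.6%), Supt4a (63.1% and 29.1%), Epm2aip1 (64.0% and 30.5%) and Vegfb (60.2% and 27.4%). In the other direction Dtx3 had 11.96% in replicate 1 and 34.5% in replicate 2. Hmox1, the inducible haem oxygenase, had no peak in replicate 1 and 21.2% in replicate 2. Klhl21 (25.4% and 45.9%), Zfp689 (33.9% and 53.4%) and Glmp (16.5% and 35.2%) followed, and 44.1% of the sequence covered in Glmp also lay in Tmem79. With 1 pool per replicate these differences have no test. Of the genes marked in 1 replicate, 894 were marked in replicate 1 alone and 120 in replicate 2 alone.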

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

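In this part the tests of gene length and of gene content on the X chromosome, and the tests of chance and of receptor families for the tallest peaks, were chosen after the result was seen.

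Signal lay outside the chromosomes used in the comparisons. Replicate 1 had 15 peaks and replicate 2 had 11 on scaffolds without a position in a chromosome, which no comparison used. No level of background was measured for them. On the scaffold chr4_GL456216_random, replicate 1 had 6 peaks with a fold enrichment of up to 5.47 and replicate 2 had 7 with up to 5.17. On chrX_GL456233_random they had 7 peaks and 1 peak.

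Genes on the X chromosome had a mean coverage of 3.99%, against 15.5% on the autosomes. Gene length was argued against as the whole cause: the X-linked mean lay at percentile 0 of 10000 length-matched autosomal lists, whose lowest mean was 11.2%. A weaker signal per X-linked gene, as 1 active copy per cell would give, is a candidate explanation: among genes with a replicated peak, the median fold enrichment of the tallest peak was 4.16 on the X chromosome and 5.86 in matched autosomal genes, at percentile 0. This value is not specific to 1 active copy, since tissue-restricted gene content could lower it as well. Genes were matched on length but not on number of peaks or covered length. The tallest of fewer peaks can be lower, so this value is not independent of the lower coverage it is meant to explain. Tissue-restricted gene content cannot be told apart: 1 of 4 X-linked members of the ubiquitous lists was marked, against 91.0% of 155 autosomal members (0.95% of permutations gave as few), but 4 genes are few, and replicated peaks lay in 28.4% of X-linked genes against 49.2% of autosomal ones. The permutations were within lists and not matched on gene length. The unmarked members were Pola1 (327389 bp), Rpl10 (2324 bp) and Ndufa1 (3576 bp).

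Of the 100 tallest replicated peaks, 23 lay in genes named Zfp, against 1.94% of all replicated peaks. Of 10000 random draws of 100 peaks, 0% gave as many (at most 8). These draws cannot exclude chance, because the pattern was first seen in the same peaks. They also treated peaks of 1 gene as independent and were not matched on peak width. A general rise of peak height toward the 3' end was argued against by draws matched on position along the gene. Of these, 0% gave as many (at most 9), with the same limits. Among peaks in Zfp genes, exact recurrence of sequence was not higher around the tallest. A mean of 0.398% of 31-base words around the summits of these 23 peaks recurred in the genome. For 2206 other peaks in Zfp genes the mean was 3.41% (the 23 lay at percentile 0.12). The median was 0 in both sets, and the Spearman's rho of fold enrichment and recurrence across peaks in Zfp genes was −0.0891. Peaks outside Zfp genes were not compared, and words had to match exactly. The test therefore does not address whether shared sequence raised peaks in Zfp genes above other peaks. Collapsed or multi-copy sequence cannot be told apart, because the 1462 olfactory and vomeronasal receptor genes tested, 0% of which held a replicated peak, had no signal that copy number could raise. No biological explanation was tested, since the design has 1 group.

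Replicate 2 covered 0.806 times as much sequence as replicate 1. A lower statistical weight of equal enrichment in replicate 2, as fewer reads or a different control would give, is a candidate explanation: at a fold enrichment of 4 to 5 its median −log10 p was 0.881 times that of replicate 1 (6.94 against 7.88). That ratio passed the bound set for it beforehand by a narrow margin only. A difference in cell type make-up between the pools cannot be told apart. The ratio of replicate 2 to replicate 1 coverage was 0.732 for visceral smooth muscle genes (percentile 2.86 of lists matched on coverage) and 0.797 for gut mesenchyme (percentile 3.73), close to the bound of 2.5, and 0.799 for gut epithelium (percentile 64.5). Values near the bound were not confined to lists of cell types, since oxidative phosphorylation genes had a ratio of 0.825 at percentile 3.81. Cell cycle genes lay at percentile 26.5 and spliceosome genes at 62.9 (rounded). Ribosomal protein genes stood out on the other side with a ratio of 0.941 at percentile 99.99.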

How the results depend on the processing

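The count of marked members was the 1 alternative added after seeing the data. All 29 list calls (9 higher, 20 not called) were the same with a q-value of 0.01, the authors' other 2 lists, peaks joined within 1 kb, each replicate left out, and random lists not matched on length. With 2 replicates, leaving out 1 moves a mean by less than 1 SD by construction. No paired analysis was possible because there is 1 group. Depth is unknown, so its effect on genes without peaks could not be measured.

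By the list mean, 17 lists were called lower. In 16 of them the median was 0 and could fall no further, which is not so for gut epithelium. Percentiles were 0 for enterocyte, goblet, Paneth or endocrine cells, enteric neural crest, neighbouring organs, central nervous system, striated and heart muscle, germ cells, Hox genes, olfactory receptors, vomeronasal receptors and defensins. They were 0.01 for endothelium and for epidermis and photoreceptors, 0.02 for gut epithelium (64.0 by the median, so the side changed), 0.05 for blood and macrophages, 0.315 for keratin-associated proteins, 1.65 for histones and 1.83 for mesothelium. By the count of marked genes, 14 lists were lower: olfactory and vomeronasal receptors at 0, Hox genes at 0.015, gut epithelium at 0.02, germ cells and defensins at 0.03, differentiated gut cells and central nervous system at 0.045, neighbouring organs at 0.07, enteric neural crest and striated muscle at 0.09, epidermis and photoreceptors at 0.1, endothelium at 0.255 and blood at 0.435. Among members with a peak, against random genes with a peak, gut epithelium lay at 0, endothelium at 0.465, Hox genes at 1.16, imprinted genes at 1.39 (95.9 among all genes), enteric neural crest at 1.58, Zfp genes at 8.50 and the signalling pathways at 86.6. Gut mesenchyme moved from 99.9 to 97.56 and kept its call of higher by a narrow margin. Visceral smooth muscle moved from 93.5 to 20.7, with no call in either. This last comparison was not possible for 13 lists with under 5 such members. The cause of these changes was not tested beyond the construction of each measure.

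The share of replicate 1 peaks overlapping replicate 2 was 62.3% at a q-value of 0.01, 64.5% with the 81074 peaks of highest −log10 p in each list, which also shortens both lists, 51.8% when 50% of the peak had to overlap and 32.3% when reciprocal. For replicate 2 the values were 83.7%, 77.8%, 70.6% and 32%. The shared sequence was 51.2% at a q-value of 0.01, 49.8% with these shorter lists and 67.0% with peaks joined within 1 kb. The correlation was 0.977 by Pearson and 0.976 in genes of at least 5 kb. Gene body enrichment was 2.15-fold at a q-value of 0.01, 2.14-fold in the list from both replicates and 2.503-fold in protein-coding genes. The ratio of bins 6 to 10 over bins 1 to 5 was 1.92 in the list from both replicates, 1.97 with joined peaks and 1.86 in genes of at least 20 kb. Marked genes numbered 2001 at a threshold of 50%, and between 4618 and 7442 under the other settings. Of 103 single genes, the mean moved by over 1 SD in 10 at a q-value of 0.01, 41 in the replicated list, 49 in the list from both replicates and 43 with joined peaks. The cause of these shifts was not tested.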

Other observations

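The values in this part were chosen after the data were seen.

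The mark ran past the annotated end of genes. For 1153 marked genes with no annotated gene in the 10 kb downstream, the first kb after the end was covered to 43.3% ± 6.42 (SD, n = 2), the second to 21.1% ± 3.89, the third to 8.92% ± 1.78 and the tenth to 0.718% ± 0.279. Upstream of 1370 marked genes with a free 10 kb, the first kb was covered to 0.0131% ± 0.0185.

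Of 6 imprinted non-coding RNAs measured, the 3 on chromosome 12 had over 25% of their length covered in each replicate, and H19, Airn and Kcnq1ot1 did not. Meg3 (109541001 to 109571726) had 55.6% ± 9.09 (SD, n = 2), Mirg 52.1% ± 10.6 and Rian 40.6% ± 12.5, and the protein-coding Rtl1 of the same region 52.0% ± 2.55. Dlk1, its neighbour, had 9.60% ± 0.141. H19 had 15.7% ± 0.892, Airn 13.5% ± 3.66 and Kcnq1ot1 3.96% ± 0.470. Of the sequence covered in Airn, 73.5% also lay in Igf2r or Mas1, and all of that covered in Kcnq1ot1 lay in Kcnq1.

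A small set of X-linked genes was marked, 36 in all. Beside Flna, the highest were Hcfc1, a regulator of cell proliferation, at 59.3% ± 1.5 (SD, n = 2), Kdm5c at 58.4% ± 9.20, Ddx3x at 55.9% ± 6.75, Maged1 at 53.6% ± 15.5, Eif2s3x at 51.1% ± 9.28 and Med12, a Mediator subunit, at 48.7% ± 0.899. Kdm5c, Ddx3x and Eif2s3x have Y-linked partners. Of these partners, Kdm5d had 2.17% ± 1.34, Ddx3y 2.01% ± 0.364 and Eif2s3y no peak. The pools were of mixed sex, so X-linked and Y-linked values are not a like comparison. Low coverage of a Y-linked gene does not show that the mark is absent in male cells.

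Of the 10 Hedgehog genes in the signalling list, a subgroup with no test of its own, Ptch1, Gli1 and Smo were marked. Ptch1 had 61.1% ± 4.57 (SD, n = 2), Gli1 36.2% ± 6.64 and Smo 31.7% ± 1.60, against 3.83% ± 0.389 in Ihh and 1.32% ± 1.86 in Shh. Ptch2 had 22.7% ± 3.60, Sufu 21.8% ± 2.00, Gli2 10.5% ± 3.60, Gli3 8.10% ± 2.30 and Hhip 2.64% ± 1.10. Among the DNA methyltransferase genes, Dnmt1 had 66.5% ± 6.81, Dnmt3a 45.5% ± 4.36 and Dnmt3b 7.45% ± 4.85.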
